A study of Hordeum vulgare with 18 samples.

How the data were processed

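RNA from barley (Hordeum vulgare) flag leaves was measured by MARS-seq, a method that sequences tags from the 3' ends of transcripts, on a NextSeq sequencer. Per the labels' protocols, each sample held 10 or more flag leaves tagged for their day of anthesis, and 3 independent samples were taken from each of 2 lines, Karl and 10_11, at 7, 14 and 21 days post anthesis. The labels do not say whether the samples of a group share pots, so the p-values measure the spread between these pooled samples. Groups were taken from the sample titles. The number at the end of a title names a sample and the labels do not say that it marks a shared block.

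The authors deposited 1 table of 13626 genes. Its raw count columns hold whole-number counts per gene and sample, per the file headers, and every gene has at least 6 counts in some library. The deposited table also holds normalized counts and a base mean, which are a signal scaled by the authors, regularized values and fold changes on the log2 scale, and a p-value and an adjusted p-value for each of 15 pairs of groups, per the file headers. Per the submitters' processing notes, bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 were used. The genome build, the annotation and the handling of molecular identifiers are not given in the sources used here. If tags were not collapsed to molecules, counts include amplification copies, so intervals and floors cover counting error only. Reads of near-identical gene copies may have been split or lost in counting, which leaves single members of gene families uncertain.

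The identifiers have the form of an annotation that the table does not pair with names, and 0 of them matched the reference gene table, so genes are given by identifier. Lists of genes chosen by function need names and were not applied. The chromosome of a gene and its order along it were read from the identifier, and 237 tested genes are unplaced. Coordinates were not used.

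Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which kept 9973 genes, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) was fitted to all 18 libraries with 1 mean for each line and day, which leaves 12 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. The comparisons, their tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. The comparisons were each pair of days within a line, the lines at each day, and the difference of the lines' changes with age. Levels are CPM, counts scaled to a common library total by TMM. The standard error of a log2 fold change was approximated as its size over the square root of the F statistic. A fold against a group at 0 uses a floor of 3 counts over the group. With 1 to 3 counts in the lower group, the ratio is given with a 95% counting interval from an exact binomial test.

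The senescence score of a library is the mean log2 CPM (prior count 2) of genes called higher in Karl at 21 d than at 7 d minus that of genes called lower. That contrast sets 21 d against 7 d libraries, but 14 d libraries enter its filter and shared spread. Scores were compared by an exact permutation test. Chromosomes were compared by Fisher's exact test with Benjamini-Hochberg adjustment, which counts genes as if they were independent. The genes named were, in each direction of 5 comparisons, the 8 called genes with the largest fold change among those with at least 20 CPM in the higher group and no overlap between the groups' libraries. The rule asked for genes with a description. As none has one, that condition was dropped and the first 2 in each direction are printed, by identifier. No overlap arises by chance in 10% of genes with 3 libraries against 3. The shares of same signs, among genes called at 21 d and between intervals, were examined after the data were seen.

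As a check of the line labels, genes that differed between the lines in the libraries of the other 2 days (chosen by a fit to those libraries among the genes that passed the filter over all 18) were used to place each library on a scale from 0, the mean of the Karl libraries, to 1, the mean of the 10_11 libraries. This check was chosen after the data were seen. It placed 1 of 18 libraries, the library labelled 10_11 14 d replicate C, with the other line. Groups were left as labelled in all main results, and counts of called genes for comparisons with 10_11 at 14 d, and the 14 d score, are also given without this library.

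The alternatives were DESeq2 1.42.0 and its size factors, no filter, a fold of at least 2, the libraries of the compared groups alone, a replicate block, and leaving out each library in turn. Counts thinned to the smallest library total and a line effect averaged over the 3 days were added after the data were seen, as were fold bounds without each library. Libraries of a group differed by more than the sampling noise of independent counts, with a chi-square per degree of freedom of 3.23 to 21.3 over 18 pairs. None was counted as a duplicate. If counts include amplification copies, these values could be raised between technical duplicates too, so they do not exclude duplicates.

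The procedure was tested on simulated counts with 200 of 9973 genes changed, 100 by each fold. In the simulation of Karl at 21 d against 7 d, edgeR recovered 76% of the genes changed 4-fold and 10% of those changed 2-fold, with 5 false calls. For the lines at 7 d these were 56% and 6%, with 2 false calls. For the lines at 14 d they were 83% and 14%, with 4 false calls, and for the lines at 21 d 89% and 17%, with 6 false calls. Changes of 2-fold were thus mostly missed in these simulations. The share of genes recovered depends on how many genes change, and 2118 were called in Karl at 21 d against 7 d. The simulated shares therefore do not give the recovery in the comparisons of days.

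The authors' deposited table was compared with these results. In 13 of its 15 comparisons the adjusted p equals the Benjamini-Hochberg value of the deposited p within 1e-06. In the authors' deposited table, Karl against 10_11 at 7 d has 64 genes with an adjusted p under 0.05, where Benjamini-Hochberg adjustment of the deposited p-values gives 35. For Karl at 7 d against 10_11 at 21 d these are 400 and 3030.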

Results

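Flag leaves of 2 barley lines, the cultivar Karl and 10_11, known as a near-isogenic line of Karl, were sampled at 7, 14 and 21 days post anthesis, a period over which the leaf senesces, with 3 libraries for each line and day. The 18 libraries held 353982 to 3231258 counts. Those of 7 d held 353982 to 947762 counts and those of 14 d and 21 d held 1058777 to 3231258. The libraries of 7 d also carry another numbering style and another range of well-like codes in the labels than those of 14 d and 21 d, so a difference between 7 d and a later day crosses these differences as well. The labels do not say whether the 7 d libraries were prepared or sequenced apart from the others. Comparisons of 21 d with 14 d and of the lines at each day do not cross that difference in the labels.

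1 library did not match its line at genes that differ between the lines. With 76 genes chosen by a fit to the 7 d and 21 d libraries, the library labelled 10_11 14 d replicate C had a median position of 0.0609 on the scale from Karl (0) to 10_11 (1). The other 10_11 libraries of all days lay at 0.873 to 1.00 and the Karl libraries at -0.0649 to 0.219. HORVU6Hr1G057380 had 165 and 224 CPM in 10_11 14 d replicates A and B and 3.54 CPM in the library labelled replicate C, against 0 counts in every Karl 14 d library. HORVU2Hr1G007080 had 2.71 and 3.24 CPM in replicates A and B and 104 CPM in the library labelled replicate C, against 80.9 to 125 CPM in Karl at 14 d. Counts of called genes for comparisons with 10_11 at 14 d, and the 14 d score, are therefore given with and without it, and other values for 10_11 at 14 d include it.

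**Figure D1:**
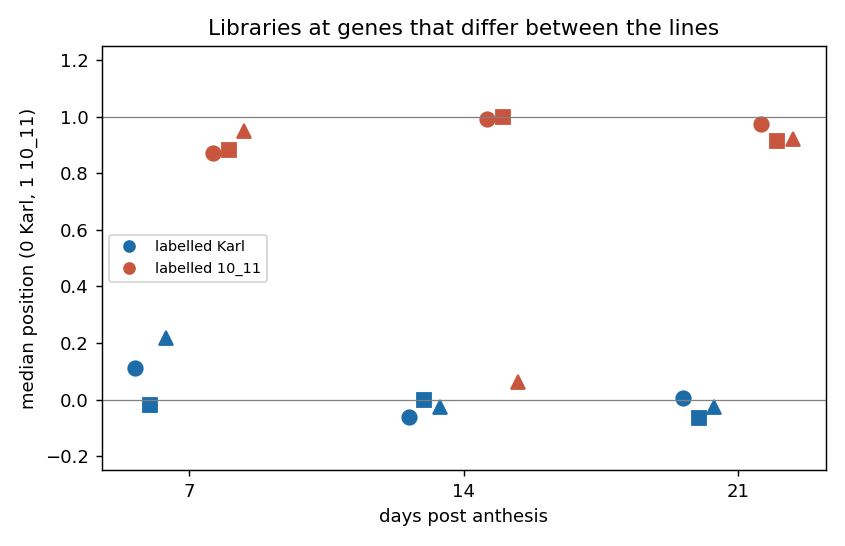
Median position of each library (1 point per library) between Karl at 0 and 10_11 at 1, over genes that differed between the lines on the other 2 days, by days post anthesis. The library labelled 10_11 14 d replicate C lies at 0.0609, among the Karl libraries.

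The first question was how transcript levels changed with leaf age in Karl. Between 7 d and 21 d, 1035 genes rose and 1083 fell of 9973 tested, and 826 and 802 of them changed at least 2-fold. By the rule for named genes, the 2 with the largest rise were HORVU1Hr1G021680 and HORVU2Hr1G122590, and the 2 with the largest fall HORVU5Hr1G011730 and HORVU6Hr1G024230. HORVU1Hr1G021680 rose from 0 counts at 7 d to 12.5 ± 6.57 CPM at 14 d and 28.8 ± 7.06 CPM at 21 d (SD, n = 3), at least 17.8-fold (edgeR adjusted p = 0.000335). HORVU2Hr1G122590 rose from 0 counts to 22.3 ± 2.03 CPM, at least 14.4-fold (SD, n = 3; edgeR adjusted p = 0.00209). HORVU5Hr1G011730 fell from 128 ± 204 CPM to 0 counts (SD, n = 3; edgeR adjusted p = 0.00359), but 1 library, Karl 7 d replicate 2, held 364 CPM against 4.07 and 17.0 CPM. The fall was at least 226-fold with all libraries, at least 20.9-fold without replicate 2, with an edgeR adjusted p of 0.0706, and at least 361-fold without replicate 1. HORVU6Hr1G024230 fell from 455 ± 162 CPM to 0.393 ± 0.342 CPM (SD, n = 3), a ratio of 1405 with a 95% counting interval of 388 to 11620 and an edgeR adjusted p of 0.000206. Its log2 fold change was -10.12, and -9.39 without Karl 21 d replicate B. Of the 100 genes with the highest mean level, 49 fell and 7 rose, and their share of counts was 48.8% ± 2.07 at 7 d, 37.2% ± 1.44 at 14 d and 34.2% ± 1.94 at 21 d (SD, n = 3). With counts thinned to the smallest library total, 436 genes were called in place of 2118.

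In Karl more genes were called in the first interval than in the second, a difference between intervals that was not itself tested. From 7 d to 14 d, 557 genes rose and 504 fell, and from 14 d to 21 d 44 rose and 53 fell. The first count was 485 without Karl 7 d replicate 1, 532 without 7 d replicate 3, 520 without 14 d replicate A and 469 without 14 d replicate C. The second was 21, 42 and 24 without 14 d replicates A, B and C, and 2 and 6 without 21 d replicates A and C, and DESeq2 called 254 genes in place of 97. Without a filter the second count was 60, and with thinned counts the 2 were 172 and 15.

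In 10_11, 1490 genes rose and 1404 fell between 7 d and 21 d, and 1165 and 1145 changed at least 2-fold. HORVU5Hr1G066460 rose from 0 counts to 87.5 ± 72.9 CPM, at least 44.5-fold (SD, n = 3; edgeR adjusted p = 0.00044), with 171 CPM in replicate B and 40.4 and 50.6 CPM in the others, and at least 24.4-fold without replicate B. HORVU2Hr1G112830 rose from 0 counts to 73.0 ± 41.5 CPM, at least 36.7-fold (SD, n = 3; edgeR adjusted p = 3.68e-05). HORVU7Hr1G040380 fell from 74.9 ± 45.3 CPM to 0 counts, at least 99.0-fold (SD, n = 3; edgeR adjusted p = 2.97e-06) and at least 66.0-fold without 7 d replicate 1, and HORVU2Hr1G119090 fell from 554 ± 124 CPM to 1.17 ± 2.03 CPM (SD, n = 3), a log2 fold change of -8.99 (SE 0.87, edgeR adjusted p = 1.21e-06). At 21 d its counts all lay in replicate A, with 3.52 CPM, and the log2 fold change was -12.73 without that library (edgeR adjusted p = 1.1e-05) and -8.28 without replicate C (2.08e-05). Of the 100 most abundant genes 57 fell and 14 rose, and their share of counts went from 49.7% ± 1.53 at 7 d to 40.4% ± 1.12 at 14 d and 31.6% ± 1.59 at 21 d (SD, n = 3). With thinned counts 715 genes were called in place of 2894.

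In this line the larger number of calls lay in the later interval, and the difference between intervals was again not tested. From 7 d to 14 d 116 genes rose and 126 fell, and from 14 d to 21 d 1072 rose and 910 fell. Without the library labelled 10_11 14 d replicate C, 35 rose and 32 fell in the first interval and 984 rose and 825 fell in the second. The first count of 242 was 55, 47 and 111 without 7 d replicates 1, 2 and 3 and 98 without 14 d replicate B, and DESeq2 gave 377. The second count of 1982 was 1132 without 14 d replicate A and 960 with the 6 libraries alone, and thinned counts gave 69 and 302.

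**Figure D2:**
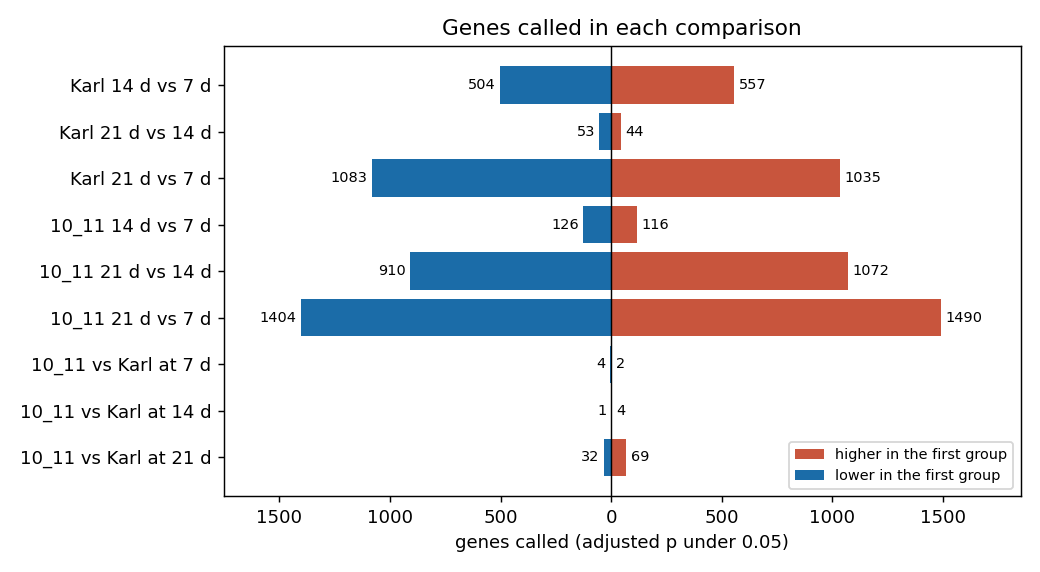
Number of genes called in each comparison (horizontal axis, genes with an edgeR adjusted p under 0.05), to the right for genes higher in the first group and to the left for genes lower in it. In Karl 1061 genes were called from 7 d to 14 d and 97 from 14 d to 21 d, against 242 and 1982 in 10_11.

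The changes with age mostly had the same direction in the 2 lines. Of the genes called from 7 d to 21 d, 756 rose in both and 804 fell in both, where independent lists of these sizes would share 155 and 152, and 4 were called in opposite directions. With thinned counts 339 genes were shared in place of 1560. Of the 1061 genes called in Karl from 7 d to 14 d, 94.7% had the same sign in 10_11 over that interval and 82.3% from 14 d to 21 d, which does not cross the difference in the labels, and of the 242 called in 10_11 from 7 d to 14 d 73.1% had the same sign in Karl from 14 d to 21 d. Without the library labelled 10_11 14 d replicate C the 3 shares were 87.4% and 87.0% of 1108 genes and 68.7% of 67. The groups of these comparisons share no library, though all enter 1 fit. Across the 9973 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.804 and a Spearman rho of 0.752.

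**Figure D3:**
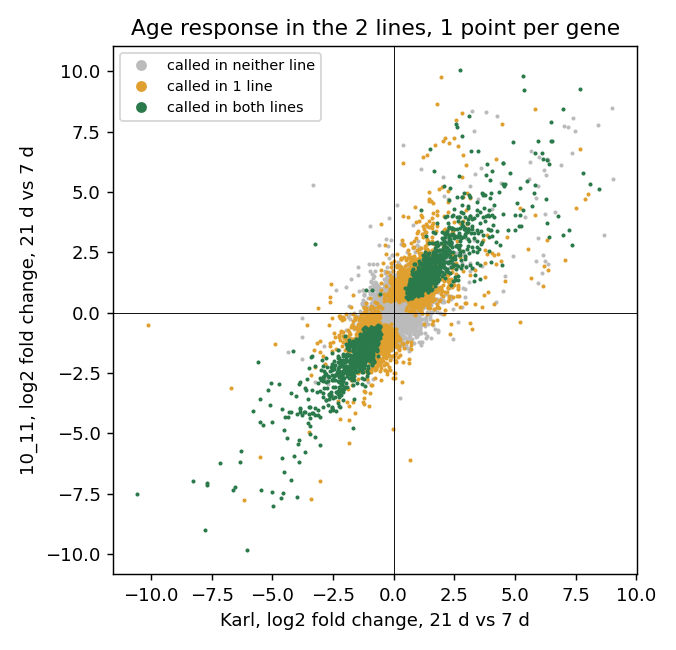
Log2 fold change from 7 d to 21 d in 10_11 (vertical) against Karl (horizontal), 1 point per tested gene, coloured by whether it was called in neither, 1 or both lines. The points follow the diagonal, with a Pearson r of 0.804.

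The test of the difference between the lines' changes called 1 gene from 7 d to 14 d and 0 from 7 d to 21 d by edgeR, with 571 and 772 genes at an unadjusted p under 0.05, and DESeq2 called 3 and 30. DESeq2 gave no p-value for the gene called by edgeR, so its 3 are other genes. Apart from the genes called by this test, a change called in 1 line and not in the other is thus not shown to differ. The called gene was HORVU6Hr1G024230, with 455 ± 162 CPM in Karl at 7 d and 0.215 ± 0.373 CPM at 14 d, and 3.96 ± 4.04 and 37.2 ± 62.8 CPM in 10_11 (SD, n = 3; edgeR adjusted p = 0.042). In 10_11 at 14 d replicate A held 110 CPM, replicate B 1.08 CPM and the library labelled replicate C 0.787 CPM. The gene count for this test was 0 without any of the libraries it uses except 10_11 14 d replicates B and C, without which it stayed 1.

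The senescence score asked whether 1 line was further along the age response at the same day. At 14 d it was -0.94 ± 0.34 in 10_11 and -0.24 ± 0.17 in Karl (SD, n = 3), a difference of -0.70 (exact permutation p = 0.1, two-sided, the smallest that 20 splits allow). With genes called in 10_11 the difference was -0.38 (exact permutation p = 0.2). The library labelled 10_11 14 d replicate C had the highest score of its group, -0.56, against -1.22 and -1.04. Without it the difference was -0.95, with the filter, the scaling and the score's genes (2158 in place of 2118) determined again. Part of that shift can thus come from the change of genes. At 7 d the scores were -2.31 ± 0.05 in 10_11 and -2.49 ± 0.04 in Karl, and at 21 d 0.94 ± 0.34 and 0.74 ± 0.19 (SD, n = 3). The Karl libraries of these 2 days also chose the genes. With genes called in 10_11 the scores at 7 d were -1.93 in 10_11 and -1.63 in Karl, the opposite order. At 21 d they were 1.46 and 0.70.

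**Figure D4:**
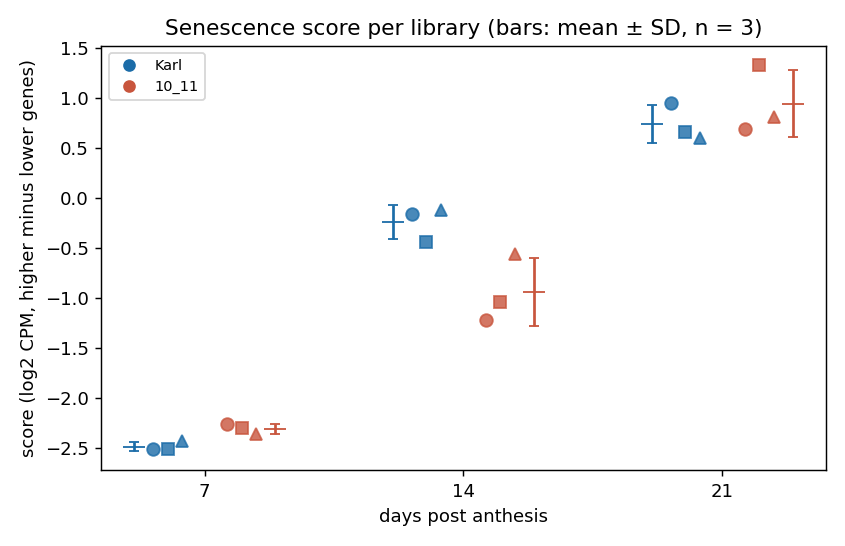
Senescence score of each library (log2 CPM of genes called higher minus genes called lower in Karl from 7 d to 21 d) by days post anthesis, with the mean and SD of each group of 3 libraries. At 14 d the 10_11 mean is -0.94 and the Karl mean -0.24. The genes were those called between the Karl libraries of 7 d and 21 d.

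The lines were compared at each day. At 7 d, 2 genes were higher and 4 lower in 10_11. HORVU6Hr1G094070 had 72.4 ± 18.2 CPM in 10_11 and 1.13 ± 0.992 CPM in Karl, a ratio of 74.5 with a 95% counting interval of 20.2 to 622, and HORVU1Hr1G087110 91.9 ± 40.5 against 3.97 ± 1.88 CPM, a log2 fold change of 4.39 (SE 0.72). HORVU2Hr1G012460 had 0.673 ± 1.17 CPM against 42.2 ± 9.50 CPM, a ratio of 67.2 with a 95% counting interval of 11.7 to 2685 (SD, n = 3; edgeR adjusted p = 0.0296 for these 3). HORVU2Hr1G009970 had 1.94 ± 1.902 CPM against 85.0 ± 27.8 CPM, a log2 fold change of -5.04 (SE 0.89, SD, n = 3, edgeR adjusted p = 0.0412). Leaving out any 1 of the 6 libraries of 7 d ended the call of all 4, with edgeR adjusted p of 0.0509 to 0.28, and with thinned counts HORVU6Hr1G094070 alone of the 4 stayed called, the others having adjusted p of 0.146, 1 and 0.0779. The log2 fold change of HORVU6Hr1G094070 was 6.04, and 5.40 without Karl replicate 1, that of HORVU2Hr1G012460 -5.88, and -9.06 and -4.98 without 10_11 replicates 1 and 2, and that of HORVU2Hr1G009970 -5.97 without 10_11 replicate 2. The count was 0 without Karl replicate 1 or 3 or 10_11 replicate 1 or 3, 1 without replicate 2 of either line, 43 without the library labelled 10_11 14 d replicate C, which enters through the filter and the shared spread, 43 with the 6 libraries alone and 33 by DESeq2. Without that 14 d library the 4 named genes had edgeR adjusted p of 3.15e-05, 8.43e-05, 0.00191 and 0.00102.

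At 14 d, 4 genes were higher and 1 lower in 10_11. In simulated data of this comparison 83% of 4-fold changes were recovered. There every library of the group carried the change, unlike the library labelled replicate C. This share therefore does not tell how many 4-fold differences were missed. HORVU6Hr1G057380 had 131 ± 114 CPM in 10_11 and 0 counts in Karl, at least 248-fold, and HORVU6Hr1G028590 had 62.2 ± 50.6 against 2.14 ± 0.964 CPM, a log2 fold change of 4.86 (SE 0.81, SD, n = 3, edgeR adjusted p = 0.0327 for both). HORVU6Hr1G026370 had 4.54 ± 3.91 CPM against 53.2 ± 33.6 CPM, a log2 fold change of -3.50 (SE 0.62, SD, n = 3, edgeR adjusted p = 0.0447). These 3 lost their call without Karl replicate A or C or 10_11 replicate A or B, the first 2 also without Karl replicate B, with edgeR adjusted p of 0.0519 to 0.368. With the 6 libraries alone none of the 3 was called (0.124, 0.119 and 0.118), and with thinned counts HORVU6Hr1G026370 was not (0.193). Without the library labelled 10_11 14 d replicate C their adjusted p was 9.06e-08, 5.64e-07 and 0.00255, and the log2 fold change of HORVU6Hr1G026370 was -4.46. Without the library labelled 10_11 14 d replicate C, 101 genes were higher and 210 lower in 10_11, 54 and 123 of them at least 4-fold. Of those 311 genes, 130 were also called in Karl from 7 d to 21 d, 122 of them with the opposite sign. The count was 0 without Karl 14 d replicate A or C, 0 without 10_11 14 d replicate A or B, 0 with the 6 libraries alone, 16 with thinned counts and 95 by DESeq2. A replicate block gave 205 genes, 58 higher and 147 lower in 10_11, but whether replicate labels mark a shared block was not decided. At an unadjusted p under 0.05 edgeR had 1346 genes.

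At 21 d, 69 genes were higher and 32 lower in 10_11. HORVU6Hr1G057380 had 92.6 ± 3.22 CPM in 10_11 and 0 counts in Karl, at least 190.6-fold (SD, n = 3; edgeR adjusted p = 0.00973). HORVU1Hr1G061550 had 54.2 ± 14.1 CPM in 10_11 and 0 counts in Karl, at least 108-fold (SD, n = 3; edgeR adjusted p = 0.015). HORVU2Hr1G007080 had 2.43 ± 2.47 CPM against 98.6 ± 22.7 CPM, a log2 fold change of -5.39 (SE 1.10, SD, n = 3, edgeR adjusted p = 0.0235), and HORVU1Hr1G089380 2.20 ± 1.96 against 23.2 ± 10.4 CPM, a log2 fold change of -3.47 (SE 0.65, SD, n = 3, edgeR adjusted p = 0.0139). These 4 lost their call without Karl replicate B, the 2 lower ones also without Karl replicate C or 10_11 replicate C, and HORVU2Hr1G007080 without 10_11 replicate A, with edgeR adjusted p of 0.051 to 0.0886. HORVU1Hr1G089380 was also not called with the 6 libraries alone (edgeR adjusted p = 0.0605) or with thinned counts (0.364). Without 10_11 replicate A the log2 fold changes of these 2 lower genes were -6.47 and -4.37. Without the library labelled 10_11 14 d replicate C, which enters through the filter and the shared spread, 96 genes were higher and 51 lower. The 4 named genes then had edgeR adjusted p of 2.02e-07, 4.95e-07, 3.42e-07 and 0.00832. The count of 101 was 46, 13 and 43 without Karl 21 d replicates A, B and C, 49 without 10_11 replicate A, 258 without 10_11 replicate B, 47 with the 6 libraries alone, 20 with thinned counts and 307 by DESeq2. Another split of these 6 libraries, with Karl replicates A and B and 10_11 replicate B on one side, called 382 genes.

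Genes called between the lines were more frequent on chromosome 6. Of 105 genes called on any day, 27 were among the 1149 tested on chromosome 6 (2.35%, against 0.884% elsewhere), an odds ratio of 2.70 with a 95% interval of 1.67 to 4.25 (Fisher's exact test, adjusted p = 0.000338 over chromosomes). Of the 105 genes 101 were called at 21 d, and of the 27 on chromosome 6 26 were, so this result rests mostly on that day. The odds ratio was 6.95 without Karl 21 d replicate B, 1.72 without the library labelled 10_11 14 d replicate C, 1.51 without 10_11 21 d replicate B and 1.78 with DESeq2 calls, and with thinned counts it was 1.65 and no longer past the threshold (Fisher's exact test, p = 0.275 before adjustment). Of 6 genes called on at least 2 days, 4 were on chromosome 6. Among genes called at 21 d, 22 of 26 on chromosome 6 had the same sign at 7 d and 14 d, against 40 of 75 elsewhere (Fisher's exact test, p = 0.00502), with the library labelled 10_11 14 d replicate C included. The tests of this paragraph count genes, which share libraries and are not independent replicates, so their p-values do not measure the spread between samples. Averaged over the 3 days, a comparison added after the data were seen, 75 genes were higher and 54 lower in 10_11, 43 of them on chromosome 6. That total of 129 was 237 without the library labelled 10_11 14 d replicate C, with 70 on chromosome 6, and 286 without 10_11 21 d replicate B, with 68.

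**Figure D5:**
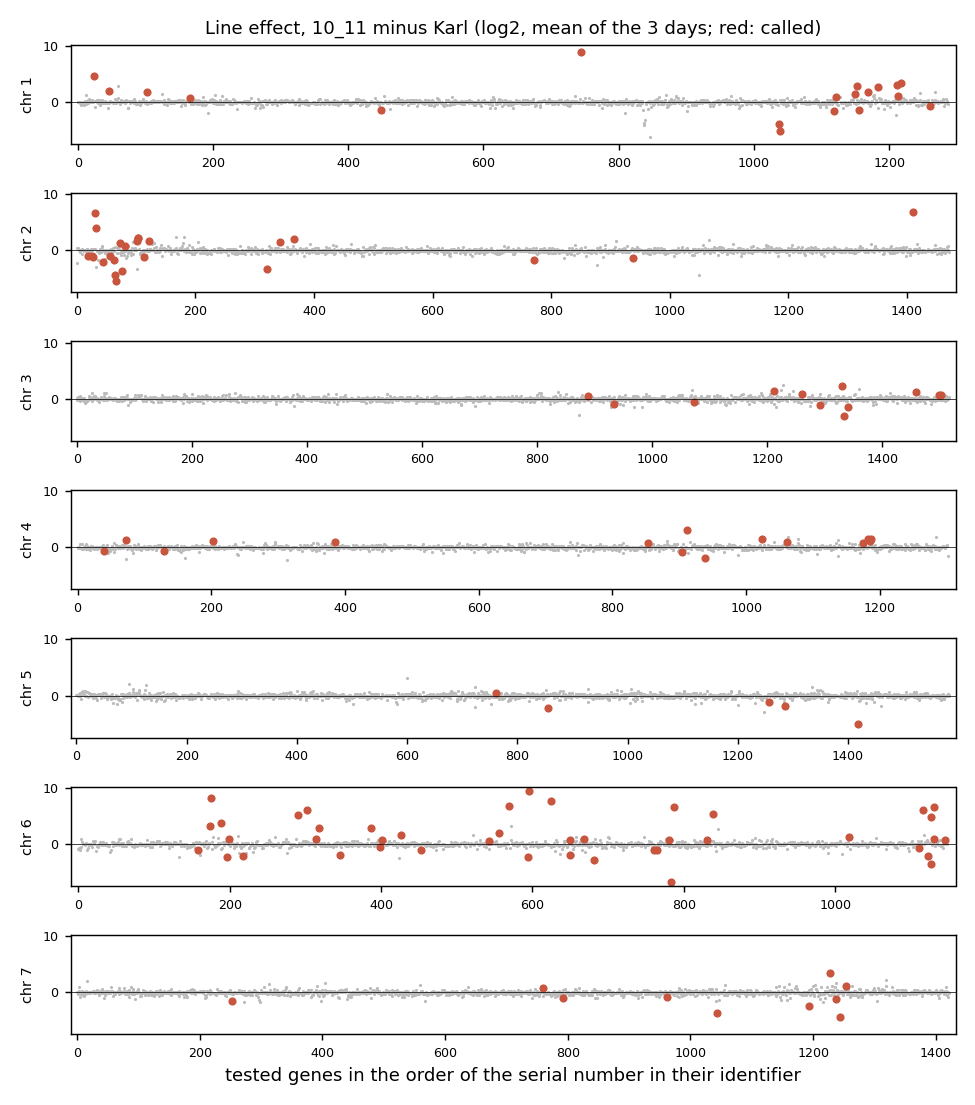
Line effect (log2, 10_11 minus Karl, averaged over the 3 days) of each tested gene on chromosomes 1 to 7, in the order of the serial number in the identifier, with the 129 called genes in red. Called genes are spread along chromosome 6, where there are 43, and gather at the start of chromosome 2.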

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

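The tests in this part were chosen after the results were seen, except the test of the difference between the lines' changes and the counts over other splits.

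HORVU6Hr1G024230 stood out because its change from 7 d to 14 d differed between the lines, by 13.91 on the log2 scale (10_11 minus Karl, edgeR adjusted p = 0.042). The fitted value depends on libraries near 0 counts. In 10_11 at 14 d, 1 library carried 110 CPM and the library labelled replicate C 0.787 CPM. Of 100 splits of the libraries into lines within day, 8 called as many genes for this difference as the 1 called, and the highest other split called 43. The 7 others among the 8 all part the lines the opposite way at 7 d and 14 d, which turns a difference between the lines into a difference of changes, so this count does not decide on chance. Of 45 other splits that part them the same way on both days, 0 called a gene. No biological or other technical explanation was tested for this gene.

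The library labelled 10_11 14 d replicate C carried Karl-like levels of genes that differ between the lines. A swap with a Karl library is argued against, since 0 of the Karl libraries lay nearer to 10_11. About equal parts of material from both lines are argued against too. At 24 genes higher in 10_11 its linear share of 10_11 was 0.0148 (quartiles 0 and 0.0480), and at 15 genes lower in 10_11 it was 0.230 (quartiles -0.0685 and 0.381). A single wrong label, or an exchange with a sample outside the series, stays open and would be consistent with its position of 0.0609, while a small admixture of 10_11 material is not excluded.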

How the results depend on the processing

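The alternatives were planned, except thinned counts, all those for the overlap, and those for the score and chromosomes other than another gene set and genes called on at least 2 days, which were chosen after the data were seen. Lists of genes were not tested, since no names are given, so camera and fry were not run. The score has too few libraries to pass a threshold, so nothing follows for its stability. DESeq2 size factors and a fold of at least 2 moved no count by more than 1.5 times. Without a filter Karl 21 d against 14 d gave 60 genes. DESeq2 gave 254 there, 377 for 10_11 14 d against 7 d, 33, 95 and 307 between the lines at 7, 14 and 21 d, and 3 and 30 for the differences of change to 14 d and 21 d. The 6 libraries alone gave 960 for 10_11 21 d against 14 d and 43, 0 and 47 between the lines. Whether replicate labels mark a shared block was not decided. Correlations of deviations of same-labelled samples were -0.32 to 0.33 over 15 pairs. Between the lines they were 0.11, -0.085 and -0.11 at 7 d and 0.091, 0.25 and 0.0081 at 14 d. At 21 d they were -0.16, 0.31 and 0.33. A replicate block gave 15 between the lines at 7 d, 205 at 14 d (58 higher and 147 lower in 10_11) and 21 for Karl 21 d against 14 d. Thinned counts hold fewer reads and gave, within Karl, 172, 15 and 436 genes (14 against 7, 21 against 14, 21 against 7), within 10_11 69, 302 and 715, between the lines at 14 d and 21 d 16 and 20, an overlap of 339, and a chromosome 6 odds ratio of 1.65 that was no longer past the threshold (Fisher's exact test, p = 0.275). Leaving out 1 library of the groups compared in turn gave 469 to 899 genes for Karl 14 d against 7 d, 2 to 123 for 21 d against 14 d, 47 to 188 and 1132 to 1809 for the same in 10_11, 0 to 1, 0 to 311 and 13 to 258 between the lines at 7, 14 and 21 d, and 0 to 1 for the difference of change to 14 d. A library of another group enters through the filter and the shared spread: without the library labelled 10_11 14 d replicate C, 43 genes were called between the lines at 7 d and 1108 for Karl 14 d against 7 d. The cause was not tested except where fewer reads or libraries enter. Of 219 alternatives for the named genes 162 stayed called, 57 did not and 0 reversed, 48 of them with a library left out, and 1 had no adjusted p in DESeq2.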

Other observations

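The tests of the 14 d score by depth and by the library labelled 10_11 14 d replicate C, and that of chromosome 6 without that library, were chosen after those values were seen. The line effect itself was added after the data were seen.

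Outside chromosome 6 the line effect was uneven as well. In identifier order, the first 147 tested genes of chromosome 2 held 18 of its 24 called genes, and the last 2 blocks of 129 tested genes of chromosome 1 held 7 and 6 of 19. Chromosome 5 held 5 of 1585 tested genes (0.315%, odds ratio 0.211, Fisher's exact test, adjusted p = 0.00011). In 100 splits of the libraries into lines within day, the line effect of 129 genes was reached by 1 split, the real one, and the highest other called 6. Random allocation of the libraries is thus argued against for that count, at the smallest share that 100 splits can give.

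Genes that differ between the lines lay close together: 83 of 128 placed genes had another called gene within 20 tested genes, where 10000 random placements gave a median of 52 and at most 79 (permutation p = 1e-04, the smallest they can give). The placements were drawn over all chromosomes together and did not keep the number of called genes on each. The excess on chromosome 6 thus enters this comparison, which does not test closeness within a chromosome by itself. Whether reads shared by similar neighbouring genes cause this closeness was not decided, since the count of 83 was not repeated without such genes. With runs of adjacent called genes counted once, chromosome 6 kept an odds ratio of 3.79 (95% interval 2.503 to 5.67). Such runs alone thus do not account for its excess of called genes, while similar genes further apart were not covered. Without the library labelled 10_11 14 d replicate C the odds ratio was 3.36 (2.49 to 4.50). A candidate explanation is that these genes lie in inherited segments that differ between the lines, which stays a hypothesis untested by sequence here. Reads of 1 line's alleles lost against the reference are argued against as the whole cause, since 65.1% of the 43 genes were higher in 10_11, while losses in either line stay open.

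The lower 14 d score of 10_11 could reflect a later age response in that line, as a hypothesis. Depth was not decided. The difference was -1.003 with thinned counts, but the score's genes were then called again, 436 in place of 2118. The library labelled 10_11 14 d replicate C is argued against, since it had the highest score of its group. Without it the difference was -0.95, also with the genes called again. With 3586 genes chosen without line labels, the 14 d difference was -0.53 with that library and -0.71 without it. Random allocation of the libraries is not excluded: with the same 3586 genes, the change from 7 d to 14 d differed between the lines by -0.46 (exact permutation p = 0.2 over 400 splits), and by -0.64 without that library (exact permutation p = 0.13 over 200 splits). At 21 d the same score was higher in 10_11 by 0.42, a difference that was not tested.

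With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave the highest count, 1 of 10, in 8 comparisons: within Karl 1061, 97 and 2118 genes against at most 0, 1 and 0 in another split, within 10_11 242, 1982 and 2894 against 0, 6 and 0, and between the lines 6 at 7 d and 5 at 14 d against 0. At 21 d 2 of 10 splits gave as many as the real 101, the highest with 382, which points to a structure of these libraries other than line. The largest correlations of deviations between libraries of different groups were also among 14 d and 21 d libraries, with -0.44 between Karl 21 d replicate C and 10_11 21 d replicate B. For the difference of the lines' changes from 7 d to 21 d, all 100 splits gave at least the real 0, which no split can miss, so the count decides nothing. The highest called 63 and parts the lines the opposite way at 7 d and 21 d, and the highest of the 50 others that part them the same way called 1.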
